A study of Drosophila melanogaster with 27 samples.

How the data were processed

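The study immunoprecipitated AGO1 from head extracts of adult flies around the day and measured RNA of the extract and of the precipitate on Affymetrix Drosophila arrays, 1 array per sample, 27 in all. Per the labels' protocols, RNA was extracted with TRIzol and labelled with biotin through the Affymetrix IVT kit. The deposited values are log2 expression values per probe set, produced with GCRMA per the submitters' processing notes; its version and the set of arrays normalized together are not given in the sources used here. The table had 18952 probe sets and no missing value, with values from 1.77 to 14.6. Array means lay between 6.40 and 6.41 in wild-type INPUT and between 5.16 and 5.18 in wild-type IP, with near-equal quantiles inside each fraction. From these values the fractions look as if they were normalized as 2 separate sets, so IP minus INPUT carries a general offset.

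Samples were grouped by fraction, genotype and time from their titles. One wild-type IP sample at ZT3 (replicate 1) has a description that names another time than its title and its time point entry, which both say ZT3; ZT3 was used. Replicate numbers of wild-type samples come from the titles. The highest correlation between any 2 arrays was 0.995, and no array repeated another.

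Control probe sets (183) were left out, leaving 18769. In the array annotation supplied with the table, 13647 (72.7%) had 1 gene symbol, 402 several and 4720 none. Of those with 1 symbol, 13544 had a gene ID that matched the RefSeq gene table and 103 did not. This named 11982 genes, 1094 of them with over 1 probe set; the probe set with the highest mean over all arrays stood for the gene. Probe sets with several symbols or none were counted but not named. Symbols are those of the annotation table, so that h appears as hry and Acp70A as SP.

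Tests used limma 3.58.1 in R 4.3.3 on the log2 values, with eBayes and Benjamini-Hochberg adjustment at 0.05. A probe set was kept when its log2 value was above 4 in at least 3 arrays, which left 15517 for wild-type tests and 15835 for tests with Tim-Dcr. Enrichment was the mean over 6 times of IP minus INPUT, from a fit of 12 fraction-by-time means to the 23 wild-type arrays (11 residual degrees of freedom). The same fit on arrays centred on their medians gave values relative to the array median. Rhythm was tested with an F test on the cosine and sine terms of a 24 h harmonic for INPUT, for IP and for their difference. Tim-Dcr was tested as an offset per fraction from the wild-type means of the same times, with all 27 arrays (13 residual degrees of freedom), and the difference of both offsets tested enrichment. Gene lists were tested with camera on deposited values at a preset correlation of 0.01, and again with an estimated correlation. The enrichment of rhythmic mRNAs was ranked among 10000 random lists matched on INPUT level in 20 bins. Tables and plots used Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.

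Groups, tests, gene lists, most alternatives and the rule for named genes were fixed before the data were examined. The rule took the 15 genes of largest positive and the 10 of largest negative enrichment past the test with 1 sign at all 6 times, the 15 (INPUT) or 10 (IP, difference) smallest rhythm p values, and the 8 highest and 8 lowest of each Tim-Dcr test with 1 sign at both times. It added every measured core clock gene for enrichment and rhythm, AGO1 and Dcr-1, and up to 4 members with the largest change in each other list. The lists were core clock, head cyclers of earlier array studies, microRNA pathway, published microRNA targets, E(spl) and Bearded families, ribosomal proteins, translation factors, oxidative phosphorylation, proteasome, photoreceptor, synaptic and neuronal, excitability channels, neuropeptides, glia, fat body, immune genes, muscle, detoxification, heat shock, midgut proteases, and germ line with reproductive tract. Those of head cyclers and microRNA targets were written from memory of the literature. A list of mitochondrially encoded genes matched 0 probe sets and was not run. The list tests on Tim-Dcr, the body-part score and camera on centred arrays were chosen after seeing the data. fry was planned and was run on centred arrays, because it tests against no change and the general offset would decide it on deposited values.

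Replicate numbers were checked for pairing of INPUT and IP. At ZT7, ZT11, ZT15, ZT19 and ZT23 the deviations of same-numbered INPUT and IP arrays from their means correlated across probe sets at 0.417, 0.394, 0.664, 0.429 and 0.381, against a median of 0.0753 between different times, where the highest was 0.405 and the lowest -0.262. The numbers in the titles were taken as pairing the samples because every same-number value was positive and far above that median, although the highest value between times exceeds those at ZT11 and ZT23. Fits with 11 wild-type pairs as a block were run beside the others; for Tim-Dcr, whose titles carry no number, only the wild-type arrays shared a block, as a random one.

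The steps were tested on simulated arrays with the spread of the real ones within fraction, time and genotype, and 200 changed probe sets. Single Tim-Dcr arrays add nothing to that spread, while the real Tim-Dcr fit also counts the difference between its ZT3 and ZT15 arrays. Noise was drawn independently, without the correlation of paired INPUT and IP arrays. Recovery in the real data can therefore differ for the Tim-Dcr tests and for differences between IP and INPUT. Enrichment recovered 36%, 68%, 96% and 100% of 1.25-, 1.5-, 2- and 4-fold changes, and called 8 unchanged probe sets. INPUT rhythm recovered 4%, 34%, 78% and 100%, and IP rhythm 2%, 36%, 82% and 98%. The Tim-Dcr tests recovered 74% of 2-fold changes in INPUT, 74% in IP and 46% in the difference of enrichment, and 100% of 4-fold changes in each. No total count or depth exists for arrays; their number limits the precision.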

Results

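The series measured messenger RNA in the heads of adult Drosophila melanogaster kept in cycles of 12 h of light and 12 h of dark, on 27 Affymetrix arrays. Each array carried either RNA of the head extract (INPUT) or RNA of the material immunoprecipitated from that extract for AGO1 (IP), the Argonaute protein that binds microRNAs in flies. Wild-type heads were collected at 6 times, 4 h apart, given as Zeitgeber time (ZT, hours after lights on). They gave 23 arrays, 11 of INPUT and 12 of IP, with 2 arrays for each fraction and time except INPUT at ZT3, which had 1. A genotype named Tim-Dcr gave 4 more arrays, 1 for each fraction at ZT3 and at ZT15; the labels do not say what that name stands for. The series' design text calls the wild-type replicates biological, and the number of arrays limits the precision of every value. Immunoprecipitates from control serum were not analysed here, so no value is corrected for non-specific binding. AGO1 and Dcr-1 had no probe set named for them alone, and neither is reported.

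The comparison of IP with INPUT asked which head mRNAs were over-represented with AGO1. The mRNAs of Vang, a membrane protein of planar cell polarity, of neur, a ubiquitin ligase of Notch signalling, and of sinu, a claudin of septate junctions, stood among the highest. Relative to the median probe set of each array, Vang was higher in IP by 3.86 on the log2 scale (SE 0.09, a 14.5-fold difference), neur by 3.47 (SE 0.10, 11.1-fold) and sinu by 3.39 (SE 0.07, 10.5-fold). The other leading genes were AdamTS-A, a metalloprotease (3.58), lncRNA:CR42549 (3.51), bip1 (3.43), ana (3.39), CG15345 (3.28), Cyp18a1, an enzyme that inactivates ecdysone (3.18), CG6583 (3.11), CG15385 (3.07), mew, an integrin alpha chain (3.04), Tes (7.99-fold), CG31710 (2.93) and jumu, a forkhead transcription factor (2.92). At the other end, Sgp lay below the median by -2.29, and lncRNA:CR42862 came next. The RNA helicase bel lay below it by -2.11, Usp32 by -2.09, the ATP synthase subunit ATPsynbeta by -2.08 and Gbeta76C, the G protein beta subunit of the eye, by -2.07. CG17560 (-2.04), CG2747 (-2.02), CG13978 (-2.01) and the glutathione transferase GstE9 (-1.99) followed.

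The deposited values of IP arrays lay below those of INPUT arrays as a whole, and the median probe set differed by -1.31 (IP minus INPUT, quartiles -1.62 and -1.02). As deposited, 563 of 15517 probe sets were higher in IP and 14443 lower (limma, Benjamini-Hochberg adjusted p under 0.05). After each array was centred on its median, 4086 were higher and 5147 lower, so the share of higher calls moved from 3.8% to 44.3%. Past 2-fold, 1165 centred probe sets were higher and 620 lower. For this reason wild-type enrichment of genes and lists is given relative to the array median, unless the deposited scale is named. Rhythm and Tim-Dcr values are on the deposited scale, unless another scale is named.

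Genes published as microRNA targets formed the group with the highest shift. All 16 measured members were higher in IP on centred arrays, and 16 also when adjusted over the list alone; as deposited, 9 were higher and 5 lower. Their median was 1.46 above the array median (2.75-fold), led by the cell death gene skl (2.47, SE 0.20), the Notch pathway glycosyltransferase fng (2.39, SE 0.09), the transcription factor sug (2.27, SE 0.11) and the repressor hry (2.18, SE 0.06). Limma's camera test gave an adjusted p of 8.03e-19, with adjusted p = 0.00549 with an estimated correlation; on centred arrays these were 9.91e-08 and 0.122. Notch target genes of the E(spl) and Bearded families followed, with a median of 1.33 (2.51-fold). Of 10 members, 8 were higher, 1 was lower and 1 did not pass, and the counts adjusted over the list alone were 8 and 1 (3 higher and 3 lower as deposited). E(spl)m3-HLH (2.30), E(spl)m2-BFM (2.13), E(spl)malpha-BFM (2.07) and BobA (1.90) led them. Camera gave adjusted p = 1.85e-08 on deposited values, and adjusted p = 0.113 with an estimated correlation. On centred arrays its adjusted p values were 0.0188 and 0.493. Clk belongs to both the target list and the core clock list.

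Muscle genes had a median of 0.25 with 5 of 13 members higher, 1 lower and 7 not past the test, and the same counts of 5 and 1 adjusted over the list alone (1 higher and 9 lower as deposited). Mlp60A (2.65), Act87E (1.15) and Mlc2 (0.97) were the members with the largest values. The camera call on this list (adjusted p = 0.0261; adjusted p = 0.867 with an estimated correlation) was lost with the paired INPUT and IP samples as a block (adjusted p = 0.170) and on centred arrays (adjusted p = 0.318).

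Transcripts of several housekeeping complexes were under-represented, though abundant mRNAs in general lay below the array median too. For INPUT levels from 8.91 to 9.88 and from 9.88 to 14.5 the median probe set lay at -0.21 and -0.22. The lists of these complexes were not compared with lists matched on level. Of 40 proteasome genes, 34 were lower and 0 higher by limma on centred arrays, also adjusted over the list alone, with a median of -0.69; Rpn1 (-1.59), Prosbeta5 (-1.41), Rpt4 (-1.40) and Rpn2 (-1.37) had the lowest values. Of 71 nuclear genes of oxidative phosphorylation, 43 were lower, 6 higher and 22 not past the test (43 and 6 adjusted over the list alone). Their median was -0.29, with ATPsynbeta at -2.08, ND-51 at -1.44, ND-75 at -1.32 and ND-B16.6 on the other side at 1.35. Of 47 translation factors, 30 were lower, 4 higher and 13 not past, against 31 and 4 adjusted over the list alone. Their median was -0.35, and the initiation factor subunits eIF3a (-1.48), eIF3c (-1.23), eIF2Bbeta (-1.17) and eIF3b (-1.09) stood out. As deposited, 40 proteasome, 70 oxidative phosphorylation and 47 translation factor genes were lower. On deposited values camera gave each of these 3 lists an adjusted p of 0.0163. The calls were lost at adjusted p = 0.867, 0.867 and 0.389 with an estimated correlation. On centred arrays camera's adjusted p values were 9.91e-08, 4.52e-04 and 4.52e-04. With an estimated correlation on centred arrays they were 0.341, 0.493 and 0.122.

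Among 17 genes of the microRNA pathway itself, 12 were lower, 2 higher and 3 not past the test, with the same 12 and 2 adjusted over the list alone and a median of -0.43. bel (-2.11), Tudor-SN (-1.26), Ge-1 (-0.95) and Dcr-2 (-0.92) had the largest values, and the list did not pass camera on deposited values (adjusted p = 0.144; adjusted p = 0.867 with an estimated correlation), though it did on centred arrays (adjusted p = 0.0155; 0.337 with an estimated correlation). Of 41 ribosomal protein genes, 29 were higher, 4 lower and 8 not past on centred arrays (29 and 4 adjusted over the list alone), against 0 higher and 41 lower as deposited, with a median of 0.30. RpS20 stood at 0.81, and RpL10Aa (-0.91), RpLP0-like (-0.86) and RpL22-like (-0.82) lay on the other side. Camera gave this list the opposite sign on deposited values (adjusted p = 0.268) and a positive one on centred arrays (adjusted p = 6.05e-04; 0.337 with an estimated correlation).

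The remaining lists did not pass limma's camera, on deposited values or on centred arrays, though single members stood far from the median. Adjusted p values given for them in this paragraph and the next are those on deposited values. Of 19 genes for potassium and other excitability channels, 9 were higher and 5 lower, with a median of 0.25; Irk1 (1.81), Sh (1.35), Shal (1.34) and SK (2.38-fold) led (adjusted p = 0.259). Of 18 photoreceptor genes, 8 were higher and 6 lower around a median of 0.12 (9 and 6 adjusted over the list alone, adjusted p = 0.406). The eye transcription factor gl (2.60) and rdgC (1.60) stood opposite inaC (-1.37) and Arr1 (-1.36). Of 21 synaptic and neuronal genes, 9 were higher and 7 lower around 0.11, with elav (1.64), cac (1.24) and brp (1.04) against Snap25 (-1.36), at an adjusted p of 0.446. Of 13 glial genes, 7 were higher and 4 lower around 0.39, with repo (1.10), nrv2 (1.02) and moody (0.91) against Gat (-1.07), at 0.543. Of 20 neuropeptide genes, 4 were higher and 8 lower around -0.15, with Nplp1 (1.17), SIFa (1.16) and ITP (0.95) against Ilp2 (-0.84), at 0.851. Of 136 detoxification genes, 33 were higher and 55 lower around -0.12 (34 and 55 adjusted over the list alone), with GstE3 (2.45) and GstE7 (1.86) against GstE9 (-1.99), at 0.420. Fat body genes (12, with 6 higher and 1 lower, median 0.11, adjusted p = 0.871) held bmm (1.37), Mtp (0.77) and Yp1 (0.75) against Lsd-1 (-1.67). Of 5 heat shock genes, 3 were higher and 0 lower around 0.71, with Hsp27 (2.29-fold), DnaJ-1 (0.79) and Hsp68 (0.71), at 0.406. Immune genes (10, with 1 higher and 2 lower, median -0.14) held PGRP-LB (2.13) and Drs (-0.83), at 0.406.

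The 13 midgut proteases had a median of -0.01 with 2 higher and 3 lower (1 and 3 adjusted over the list alone), at an adjusted p of 0.406. The 18 germ line and reproductive tract genes had a median of -0.35 with 1 higher and 8 lower, among them Mst84Da (-1.15) and SP (-0.95), at 0.999. The 19 head cyclers of earlier array studies had a median of -0.01 with 6 higher and 6 lower, at 0.506. Except where stated, counts of these lists adjusted over the list alone were equal to those over all probe sets. Camera's direction on deposited values was opposite to the sign of the centred median for the ribosomal, germ line, midgut, immune, core clock and head cycler lists. The centred mean was positive for the core clock list (0.13) and the head cyclers (0.18) while their medians were -0.04 and -0.01. With an estimated correlation on deposited values only the microRNA target list kept its camera call.

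**Figure D1:**
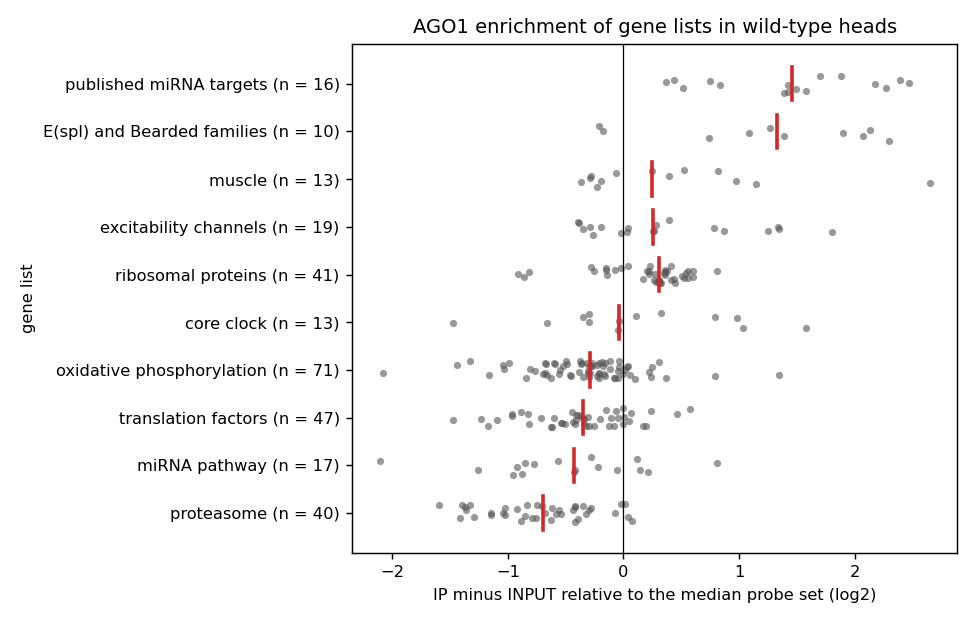
IP minus INPUT relative to the array median (log2, horizontal axis) for the members of 10 gene lists (vertical axis) in wild-type heads; each point is a gene and each red bar the list median. The medians run from 1.46 for published microRNA targets to -0.69 for proteasome genes.

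Core clock mRNAs differed from each other in their representation with AGO1. Clk, the activator at the centre of the feedback loop, was higher in IP by 1.58 relative to the array median (SE 0.06), and by 0.32 on the deposited scale. The feedback transcription factor vri (1.03, SE 0.09), the repressor cwo (0.98, SE 0.07) and jet (0.79, SE 0.08) were higher as well, and tim was higher by 0.32 (SE 0.09, limma adjusted p = 0.00621). The light receptor cry (-1.47, SE 0.09), the neuropeptide Pdf (-0.66, SE 0.09), per (-0.35, SE 0.08), cyc (-0.30, SE 0.06) and Pdfr (-0.30, SE 0.07) were lower. Pdp1 (0.11), dco (-0.04) and slmb (-0.04) did not differ from the median by the test. On the deposited scale vri, cwo, jet, tim and Pdp1 lay below INPUT, so their direction depends on the scale. As a list, 5 of 13 were higher and 5 lower, the same counts as adjusted over the list alone. Camera did not call the list on deposited values (adjusted p = 0.884) or on centred arrays (adjusted p = 0.698).

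The times of collection asked which mRNAs varied over the day. In INPUT, CG34134 had the clearest 24 h rhythm, with a peak-to-trough difference of 5.44 (log2, SE 0.18, 43.4-fold) and a peak at ZT21.3. Achl changed by 4.67 (25.5-fold, peak ZT20.4). Among clock genes, tim changed by 2.63 (SE 0.25, 6.20-fold, peak ZT15.0), vri by 2.51 (SE 0.21, 5.68-fold, peak ZT12.3), per by 2.19 (SE 0.24, 4.56-fold, peak ZT13.9), cry by 1.61 (SE 0.20, 3.06-fold, peak ZT4.45) and Clk by 1.52 (SE 0.22, 2.87-fold, peak ZT1.32). Other leading rhythmic mRNAs were Usp8 (2.56), CG42329 (2.22), CG13305 (2.14), Slob, which binds a potassium channel (1.99), CG8419 (1.85), CG42367 (1.72), CG14275 (1.57), CG32369 (1.55) and CG17560 (2.99). The smallest adjusted p of these clock genes was 1.43e-06 for vri and the largest 0.00187 for Clk (limma F test, Benjamini-Hochberg). cwo (0.59, adjusted p = 0.0825) and Pdp1 (0.59, adjusted p = 0.501) did not pass, nor did dco, Pdfr, Pdf, jet, slmb and cyc.

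In all, 92 probe sets (80 genes) passed the rhythm test in INPUT and 144 in IP. Of the INPUT rhythms, 65 peaked from ZT12 to ZT24 and 27 in the light, with a median peak-to-trough difference of 1.12 (2.18-fold). In IP, 82 peaked in the dark and 62 in the light. The 2 sets shared 67 probe sets; as INPUT and IP are fractions of paired samples, the lists are not independent. Peak times of the shared probe sets differed by a median of 0.621 h, and 95.5% lay within 2 h. A test of any difference between the 6 times called fewer, 46 in INPUT and 75 in IP, and a fit on the IP arrays alone called 56. Without INPUT ZT23 replicate 1 the INPUT count was 46, and without INPUT ZT11 replicate 1 it was 56. For IP, 5 of 100 assignments of the times to the samples, the real one included, gave a count as large, and the highest other was 1464.

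In IP, CG34134 (4.98, SE 0.18, peak ZT22.4), Usp8 (3.99), Achl (3.95), vri (3.19, SE 0.20, 9.11-fold), tim (2.86, SE 0.22), CG42367 (2.48), dy (4.60, SE 0.43, 24.3-fold, peak ZT15.7), CG13305 (2.48), CG7252 (1.88) and CG40486 (1.18) had the smallest p values. Clk (1.77, peak ZT2.17), per (1.67), cry (1.23) and cwo (0.80, limma adjusted p = 0.00193) passed in IP too, while Pdp1 (0.57, adjusted p = 0.334), Pdf, Pdfr, dco, jet, slmb and cyc did not. By list, 5 of 13 core clock genes were rhythmic in INPUT and 6 in IP (7 and 9 adjusted over the list alone). Of 19 head cyclers of earlier array studies, 7 and 9 passed (14 and 15 adjusted over the list alone). The detoxification list held 4 rhythmic genes in INPUT and 8 in IP (5 and 11 adjusted over the list alone). The photoreceptor list held 0 in INPUT by limma and 2 in IP, Galphaq and Arr1 (1 and 7 adjusted over the list alone). E(spl)m2-BFM was the 1 rhythmic member of the E(spl) and Bearded list in each fraction. Clk was the 1 rhythmic published microRNA target in each, and PGRP-LB the 1 rhythmic immune gene in IP. Members named here outside the core clock were chosen after their values were seen.

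**Figure D2:**
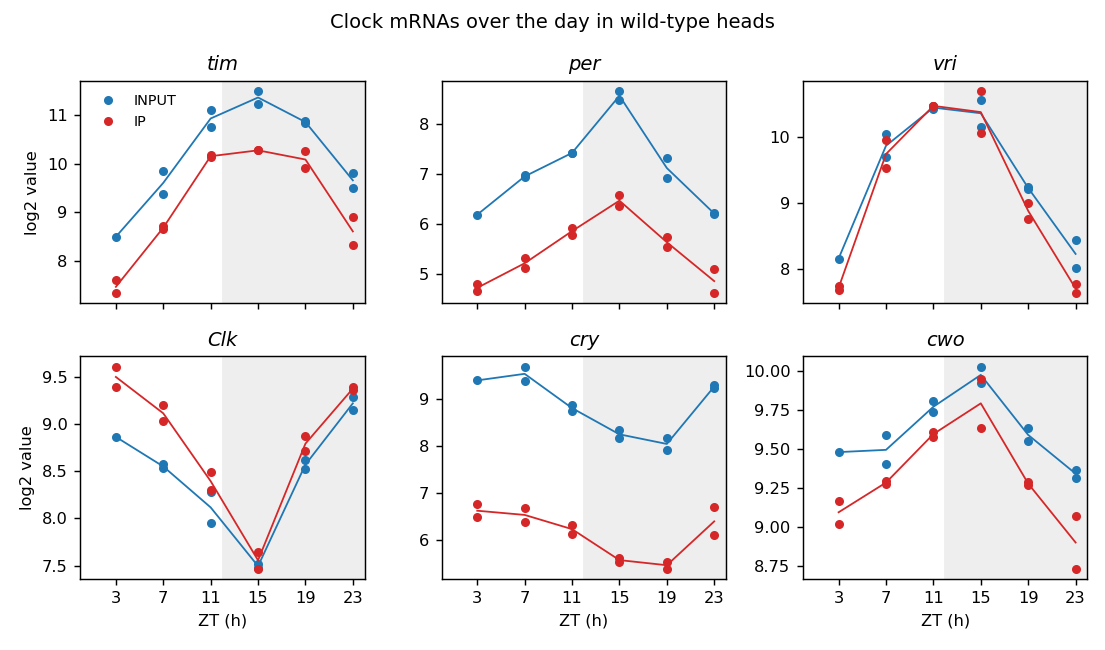
Deposited log2 values (vertical axes) of tim, per, vri, Clk, cry and cwo against ZT in hours (horizontal axes) in wild-type INPUT (blue) and IP (red); each point is an array, lines join the means per time, and the dark phase is grey. The INPUT peaks fitted for tim (ZT15.0) and Clk (ZT1.32) lie on opposite sides of the day.

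The difference between the rhythms of IP and INPUT asked whether the share of an mRNA with AGO1 varied over the day. By limma, 0 of 15517 probe sets passed this test, with 174 at an unadjusted p under 0.05. That is fewer than chance alone would give, so this test, which takes no account of pairing, looks conservative. A test of any difference between times and a fit on the paired differences each called 1. In core clock genes the largest fitted difference was that of vri (0.68, SE 0.29, unadjusted p = 0.0897), followed by per (0.54, SE 0.32). In simulated data with the same spread but no correlation within pairs, the unpaired limma test recovered 40% of 2-fold and 84% of 4-fold rhythms of enrichment. The mRNAs rhythmic in INPUT, 80 genes among them CG34134, Achl, vri and tim, had a median enrichment of 0.10 relative to the array median, while random lists matched on INPUT level had -0.10 (95% of them from -0.26 to 0.08). This lies at percentile 98.3 of 10000 random lists (two-sided permutation p = 0.0344). With 1 array left out at a time the call was lost in 19 of 23 cases, that is for every array except IP ZT3 replicate 1, IP ZT7 replicate 2 and both IP ZT15 arrays. The median was -0.042 without INPUT ZT15 replicate 2 (two-sided permutation p = 0.537).

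The Tim-Dcr arrays were compared with wild-type arrays of the same times. In INPUT the genes named for the lowest values included BG642312, lower by -7.27 (log2, SE 0.29), Acp98AB by -6.75 (SE 0.93), the ejaculatory duct peptide Dup99B by -6.54, the ejaculatory bulb protein EbpII by -6.53, the sex peptide SP by -6.52 (SE 0.46) and CG17376 by -6.52. Cyp4g1, an enzyme of hydrocarbon synthesis in oenocytes, was lower by -6.83 (SE 0.70) and CG4836 by -6.19. Higher in Tim-Dcr were Osi6 (3.45, SE 0.22), CG12947 (3.41, SE 0.13), CG8012 (2.82), CG31219 (2.77), the storage protein Lsp2 (2.72, SE 0.71, limma adjusted p = 0.00461), obst-A (2.72), CG11741 (2.53) and CG10560 (2.44). In IP, Osi6 (3.34), CG12947 (3.10), Lsp2 (2.49), CG13678 (2.31), Blimp-1 (2.30), CG31219 (2.29), CG8012 (2.16) and CG3857 (2.16) were higher. Acp98AB (-7.06), BG642312 (-6.41), SP (-5.93), Dup99B (-5.85), EbpII (-5.74), Acp53C14b (-5.72), the trypsin alphaTry (-5.70) and Cyp4g1 (-5.57) were lower there. At ZT15 most Tim-Dcr readings of these lower genes were near background, for example 4.15 in INPUT and 2.62 in IP for SP, and 3.59 and 2.70 for BG642312. The sizes of these differences are therefore not exact, and their order has no meaning. CG17376 and CG4836 lost their INPUT call without the Tim-Dcr INPUT array at ZT15, and Lsp2 lost its INPUT call without that array. In IP, Lsp2 lost its call without either Tim-Dcr IP array (adjusted p = 0.0753 without ZT3 and 0.0591 without ZT15, limma).

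Transcripts known from other body parts were lower in Tim-Dcr than in the wild-type head arrays. Mst84Db, a sperm protein transcript, averaged 12.8 ± 0.195 (SD, n = 11) in wild-type INPUT and read 9.88 at ZT3 and 4.44 at ZT15 in Tim-Dcr. SP averaged 11.8 ± 0.210 and read 6.64 and 4.15. alphaTry averaged 12.1 ± 0.217 and read 7.51 and 4.73. Of 18 germ line and reproductive tract genes, 14 were lower and 0 higher by limma in INPUT (median -4.42), and 13 of 13 midgut proteases were lower (median -2.70), the same numbers as adjusted over each list alone. Camera gave these lists adjusted p values of 3.82e-09 and 2.00e-07, each with adjusted p = 0.417 with an estimated correlation. Among wild-type arrays, IP ZT3 replicate 2 had the lowest mean of both lists, -1.001 relative to its fraction. The yolk protein transcript Yp1, the neuronal elav, the glial repo and the photoreceptor chp read above the wild-type INPUT mean in both Tim-Dcr INPUT arrays; elav averaged 9.87 in wild type and 10.4 in Tim-Dcr, and repo 9.90 and 10.8. Other markers of neurons and photoreceptors did not move with them: nSyb averaged 10.9 in wild type and 10.7 in Tim-Dcr, trp 12.1 in both and Arr1 13.2 in both. These 7 markers were chosen after their values were seen.

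**Figure D3:**
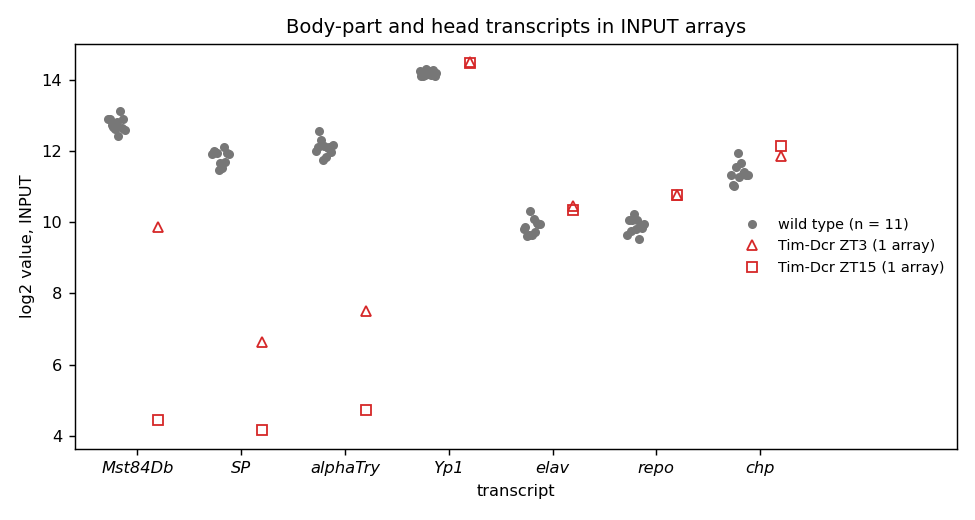
Deposited log2 values in INPUT arrays (vertical axis) of 7 transcripts (horizontal axis); grey points are the 11 wild-type arrays, and the red triangle and square are the single Tim-Dcr arrays at ZT3 and ZT15. Mst84Db, SP and alphaTry lie below every wild-type array in both Tim-Dcr arrays.

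Beside these body-part transcripts, other gene lists differed; over all probe sets the median difference in INPUT was 0.23, or 0.44 on centred arrays. Neuropeptide genes lay above that median by 0.62, with 14 of 20 higher and 0 lower by limma (15 adjusted over the list alone), led by Ilp5 (2.02), Nplp3 (1.33), Ilp2 (1.26) and Nplp4 (1.16). Camera gave an adjusted p of 0.00353 (adjusted p = 0.417 with an estimated correlation). Glial genes lay above it by 0.45, with 8 of 13 higher (10 adjusted over the list alone), among them Glt (1.60), Gat (1.45), moody (1.03) and e (1.02), at an adjusted p of 0.0218 (adjusted p = 0.499 with an estimated correlation). Proteasome genes lay below by -0.89, with 27 of 40 lower and 0 higher by limma. Camera called them at adjusted p = 4.43e-09 (adjusted p = 0.417 with an estimated correlation). Prosbeta5R1 (-3.81), Prosalpha6T (-3.46), Rpn13R (-2.78) and Rpn12R (-2.65) led them. Prosbeta5R1 and Prosalpha6T are testis forms, and whether other members of the list are was not checked. The decrease of this list was thus not told apart from that of sperm transcripts such as Mst84Db. Oxidative phosphorylation genes lay below by -0.26, with 20 of 71 lower and 1 higher as deposited, against 17 lower and 19 higher on centred arrays. COX7AL (-4.81), COX5BL (-4.72), COX4L (-4.54) and UQCR-11L (-3.97), paralogs known from the testis, had the largest values, beside the lower sperm transcripts such as Mst84Db (adjusted p = 0.00788; adjusted p = 0.547 with an estimated correlation). Immune genes lay below by -1.21, with 4 of 10 lower, led by Drs (-2.31), Mtk (-1.74), DptB (-1.74) and AttD (-1.60), at 0.00914 (adjusted p = 0.499 with an estimated correlation). Detoxification genes, 59 higher and 14 lower, lay near the median of all probe sets (0.09), at 0.0324 (adjusted p = 0.547 with an estimated correlation). Of 13 core clock genes, 4 were higher in INPUT, Pdf (1.09), jet (0.70), Pdfr (0.49) and cyc (0.46), and 7 on centred arrays. Centred counts of higher genes were 18 for neuropeptides, 11 for glia and 84 for detoxification (9 lower), and those of lower genes 24 for the proteasome and 4 for immune genes. Synaptic genes (11 of 21 higher), fat body genes (8 of 12 higher) and photoreceptor genes (9 of 18 higher, 1 lower) did not pass camera, nor did the lists not named here.

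In IP the germ line and reproductive tract genes (median -3.77, 14 of 18 lower) and midgut proteases (-1.95, 12 of 13 lower) were lower as well, at camera adjusted p values of 1.79e-08 and 6.09e-07 (both with adjusted p = 0.388 with an estimated correlation). Over all probe sets the IP median differed by 0.17, or 0.49 on centred arrays. Ribosomal protein genes lay below that median by -0.41, with 18 of 41 lower and 0 higher by limma as deposited (19 lower adjusted over the list alone), against 8 lower and 9 higher on centred arrays (adjusted p = 2.22e-04; adjusted p = 0.388 with an estimated correlation). Proteasome genes lay below by -0.53, with 18 of 40 lower and 2 higher, against 15 and 10 on centred arrays (adjusted p = 0.00136; adjusted p = 0.467 with an estimated correlation). Oxidative phosphorylation, immune, neuropeptide and detoxification genes passed camera in IP too, in the direction they had in INPUT as deposited (on centred arrays 26 oxidative phosphorylation genes were higher and 15 lower), at adjusted p values of 0.00873, 0.00139, 0.00696 and 0.00834; with an estimated correlation these were 0.467, 0.402, 0.402 and 0.467.

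As a count, 7805 of 15835 probe sets passed in INPUT, 5118 higher and 2687 lower in Tim-Dcr, and 6961 in IP, 4270 higher and 2691 lower (limma). On centred arrays 8336 were higher and 2324 lower in INPUT, and 9380 higher and 1940 lower in IP, which moved the share of higher calls from 65.6% to 78.2% and from 61.3% to 82.9%. Each time had a single Tim-Dcr array, so the spread comes from all 27 arrays together, and genotype cannot be told apart from how those samples were made. Without the Tim-Dcr INPUT array at ZT15 the INPUT count was 3916, and without the Tim-Dcr IP array at ZT15 the IP count was 3025.

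The last comparison asked whether enrichment with AGO1 differed between the genotypes. It was higher in Tim-Dcr by 2.63 for Gld2 (SE 0.46, limma adjusted p = 0.0121), 2.35 for CG15531, 2.22 for CG17562, 2.03 for CNT1, 1.94 for CG33287, 1.92 for the dynein heavy chain Dnah3, 1.88 for CG13978 and 1.75 for CG13501 (SE 0.23, adjusted p = 0.00277). All 8 of these genes were lower in Tim-Dcr INPUT, from -1.99 for CG13501 to -3.80 for CG15531, and their 16 Tim-Dcr INPUT readings lay between 3.99 (CG33287) and 5.91 (CG13978). Relative enrichment of wild-type probe sets varied less at low INPUT levels, with an SD of 0.198 from 3.64 to 4.19, 0.269 from 4.19 to 4.66, 0.453 from 4.66 to 5.37 and 0.665 from 5.37 to 6.18, against 0.819 from 6.91 to 7.59. Near background, IP minus INPUT thus lay close to the array median for most probe sets. A gene below that median in wild type, such as CG13978, could read as higher in Tim-Dcr from its low INPUT level alone. Both the size and the sign of these 8 differences are therefore uncertain. Enrichment was lower in Tim-Dcr by -1.88 for CG7142, which read 4.58 in both Tim-Dcr INPUT arrays, as low as those genes. The others were CG15385 (-1.83), the sex determination gene dsx (-1.75, SE 0.37), l(2)41Ab (-1.74), the homeobox gene Dr (-1.65), CG5466 (-1.62), CG13252 (-1.56, limma adjusted p = 0.00791) and lov (-1.54). CG15531 lost its call in 20 alternative settings, and the other genes named for this test in 4 to 7. Of the lists, published microRNA targets had a median difference of -0.62, with 1 of 16 members lower and 0 higher by limma (4 lower adjusted over the list alone). wls (-1.02, adjusted p = 0.0485) was that member, while sens (-1.43), ex (-0.95) and skl (-0.91) did not pass. Ribosomal protein genes had a median of -0.27, with 2 of 41 lower (10 adjusted over the list alone), RpLP2 (-0.55) among them. Their median was -0.15 on centred and -0.086 on quantile-normalized arrays. Proteasome genes had a median of 0.35, with 1 of 40 higher. This list lay below the array median in wild type (-0.69), and 27 of its members were lower in Tim-Dcr INPUT. The limit given above for low INPUT readings may therefore hold for part of it. The call of wls and those of the 2 ribosomal protein genes were lost on centred and on quantile-normalized arrays. Camera called these 3 lists at adjusted p values of 0.0186, 0.00309 and 1.17e-06, each with adjusted p = 0.910 with an estimated correlation.

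In all, 432 probe sets passed, 125 higher and 307 lower in Tim-Dcr, against 105 higher and 61 lower on centred arrays, where the median of all probe sets moved from -0.02 to 0.10. With the 11 wild-type pairs as a random block, chosen after seeing the data, 720 passed, 208 higher and 512 lower. With the arrays at ZT3 and ZT15 alone 5 passed, and the 16 genes named lost their call. Single arrays decided this count: it was 12 without the Tim-Dcr IP array at ZT3, 15 and 29 without the Tim-Dcr INPUT array at ZT15 or ZT3, and 676 without the Tim-Dcr IP array at ZT15. Without wild-type INPUT ZT15 replicate 1 or 2 it was 243 or 698, without IP ZT3 replicate 1 or 2 it was 258 or 268, and without IP ZT15 replicate 1 or 2 it was 934 or 210. Leaving out the only wild-type INPUT array at ZT3 needed another fit, with fraction and time as separate terms, and gave 1457.

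Across 15835 probe sets, enrichment at ZT3 and ZT15 in wild type and in Tim-Dcr had a Pearson r of 0.751 and a Spearman rho of 0.649; probe sets are not independent replicates, and no p is given. Of 1165 probe sets at least 2-fold higher on centred wild-type arrays, 1126 (96.7%) lay above the array median in both Tim-Dcr pairs. Of 620 at least 2-fold lower, 500 (80.6%) lay below it in both. The same shares over all probe sets were not counted. At ZT3 alone r was 0.626.

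**Figure D4:**
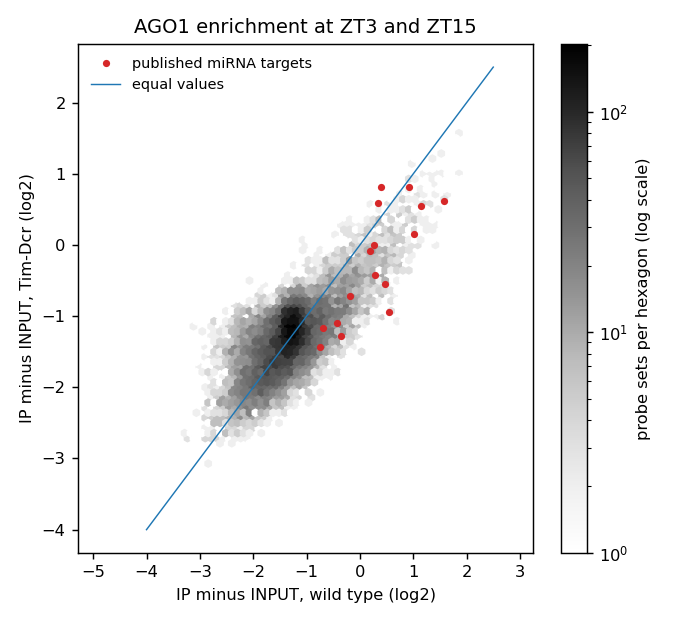
IP minus INPUT (log2, deposited values, mean of ZT3 and ZT15) in wild type (horizontal axis) and Tim-Dcr (vertical axis) for 15835 probe sets, shaded by their number per hexagon on a log scale; red points are the published microRNA targets and the blue line marks equal values. The relation has a Pearson r of 0.751. With enrichment taken relative to the median of each genotype and time, which is not the plotted scale, 14 of the 16 targets were less enriched in Tim-Dcr.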

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

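The tests on body-part transcripts and on gene lists in Tim-Dcr were chosen only after the result was seen. Enrichment with AGO1 differed between genotypes by limma's test of the difference itself for 432 probe sets, which moved to 5 with the arrays at ZT3 and ZT15 alone. Fitted enrichment was higher in Tim-Dcr for Gld2 (2.63), CG15531 (2.35), CG17562 (2.22), CNT1 (2.03), CG33287 (1.94), Dnah3 (1.92), CG13978 (1.88) and CG13501 (1.75). All of these read between 3.99 and 5.91 in Tim-Dcr INPUT, low readings that leave the size and the sign of these differences uncertain. Enrichment was lower for CG7142 (-1.88), with an equally low reading of 4.58. It was also lower for CG15385 (-1.83), dsx (-1.75), l(2)41Ab (-1.74), Dr (-1.65), CG5466 (-1.62), CG13252 (-1.56) and lov (-1.54). By camera with a preset correlation, the lists of ribosomal proteins (median -0.27), proteasome (0.35) and published microRNA targets (-0.62) passed too. Each call was lost at adjusted p = 0.910 with an estimated correlation. Low readings in Tim-Dcr INPUT may bear on part of the proteasome list as well.

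The smaller enrichment of published microRNA targets in Tim-Dcr may not be particular to them. Enrichment was taken here relative to the median probe set of each genotype and time, unlike the -0.62 above, which is on the deposited scale. At the 4 times not compared with Tim-Dcr, 1397 other genes had wild-type enrichment within the quartiles of that list (0.74 to 2.02). At ZT3 and ZT15 those genes differed by a median of -0.517 (Tim-Dcr minus wild type, 1.21 against 0.75), and 90.1% of them were less enriched in Tim-Dcr. The targets differed by a median of -0.65 (medians of 1.03 in Tim-Dcr and 1.63 in wild type), and 14 of 16 were less enriched. Their median difference lay at percentile 11.8 of random lists of those other genes. The targets started from a higher enrichment than the other genes, so the sizes of the 2 differences are not matched on it. A weaker precipitation of all AGO1-associated mRNAs in the Tim-Dcr samples and a general effect of the genotype both stay open, since each time had 1 Tim-Dcr array.

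Body-part transcripts were far lower in the Tim-Dcr samples: of the 2 body-part lists, 19 members had a wild-type INPUT mean above 8, and 100% of them were lower in Tim-Dcr. That share counts the decrease that raised the question, so it cannot decide whether RNA from other body parts was in the wild-type head collections. Levels in wild-type INPUT do not rest on that decrease. There Mst84Db read above a median of 99.1% of probe sets, alphaTry above 98.5% and SP above 98.3%. The neuronal elav read above 91.4% and the photoreceptor Arr1 above 99.5%, but the germ line transcript vas above only 9.92%. Body-part transcripts such as the first 3 were thus abundant in these collections. No heads known to be free of other body parts were compared, so their source stays open, as does an untested effect of the genotype. A different share of males does not account for the midgut proteases, which are not particular to males and had a median of -2.70; for the reproductive genes it cannot be told apart, because the ovary transcript osk (-2.65, adjusted p = 0.0819 by limma) and the female yolk protein transcript Yp1 (0.27) had opposite signs. After quantile normalization of all arrays the higher list median was -2.48. Deposited INPUT arrays already had near-equal means, 6.375 to 6.376 in Tim-Dcr and 6.402 to 6.413 in wild type. That step could therefore move a list little, and it cannot decide on normalization as a cause. Array medians were 5.66 to 5.93 against 6.11 to 6.19, so a general shift between deposited INPUT arrays was far smaller than the list medians.

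Published microRNA targets were over-represented with AGO1. Their median of 1.46 lay at percentile 100 of random lists matched on INPUT level (95% of them from -0.38 to 0.31), and at percentile 100 of lists matched on the span of the gene (-0.31 to 0.48), with a span for 16 of 16. Both values argue against expression level and gene span as the whole cause. Binding of mRNA to the beads or antibody without AGO1 stays open, as no control precipitate was analysed here, and microRNA sites were not searched.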

How the results depend on the processing

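Alternatives chosen after seeing the data were centring with the pair block, leaving out 3 wild-type arrays, the body-part score, camera on centred arrays, the pair block for Tim-Dcr and the list tests on Tim-Dcr; all other settings were planned. Centring each array gave 4086 higher and 5147 lower probe sets for enrichment, quantile normalization 4127 and 5226, and centring with the pair block 4640 and 6008; a general shift of the array moves all probe sets by construction. In these 3 settings, in that order, the deposited sign turned for cwo (0.98, 0.91, 0.98), Pdp1 (0.11, 0.088, 0.11), tim (0.32, 0.30, 0.34), jet (0.79, 0.85, 0.81) and vri (1.03, 0.99, 1.04). A mean above 6 as filter left 7436 lower probe sets, 4938 for Tim-Dcr in INPUT and 3613 in IP, with fewer probe sets tested. A 2-fold minimum left 108 higher, 2849 and 2093 for Tim-Dcr in INPUT and IP, and 208 for the difference. Centring gave 11320 for Tim-Dcr in IP and 166 for the difference. Using ZT3 alone for Tim-Dcr gave 4086 (INPUT), 3147 (IP) and 11 (difference), ZT15 alone gave 4 for the difference, arrays at ZT3 and ZT15 only gave 5, all with fewer arrays, and leaving out the 3 wild-type arrays nearest Tim-Dcr gave 262.

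The test over 6 times called 46 rhythms in INPUT, 75 in IP and 1 of enrichment, and the fit on IP alone 56; the cause was not tested. The replicate block of 11 pairs gave 601 higher and 14558 lower, the paired differences gave 1 rhythm of enrichment, and the number as a term gave 133 rhythms in INPUT and 202 in IP. As a random block over wild-type arrays it gave 7350 (INPUT), 6770 (IP) and 720 (difference) for Tim-Dcr. The block ended the call of the muscle list (5 lists past against 6), moved the Tim-Dcr difference from 432 to 720, and moved no other count by over 1.5 times, apart from the 1 rhythm of enrichment in the paired differences, a fit of another form without the unpaired array; with the number as a term it stayed at 0. Gene lists past camera fell from 6 to 1 with an estimated correlation and to 0 on centred arrays with an estimated correlation (7 with the preset one), and fry on centred arrays called 16. As signed -log10 p, the ribosomal list turned to 9.004 (fry) and 3.84 (camera on centred arrays) and the germ line list to -1.81 (fry). The median enrichment of rhythmic mRNAs was 0.11 for genes of the test over 6 times (two-sided permutation p = 0.117, fewer genes) and -0.012 for the clock and head cycler lists (permutation p = 0.437), and 0.037 for 282 genes at an unadjusted p under 0.01 (permutation p = 0.0026). At ZT3 alone the correlation of genotypes was 0.626.

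Leaving out 1 array at a time gave 521 to 582 higher and 14400 to 14454 lower probe sets, 46 to 115 rhythms in INPUT, 96 to 148 in IP and 0 to 0 of enrichment (limma, 174 at an unadjusted p under 0.05 with all arrays). It gave -0.042 to 0.15 for the enrichment of rhythmic mRNAs, r from 0.716 to 0.766, and 3916 to 8237 (INPUT), 3025 to 8175 (IP) and 12 to 1457 (difference) for Tim-Dcr. The highest Tim-Dcr counts come from leaving out wild-type INPUT ZT3, where an additive fit took the place of the usual one; INPUT ZT23 replicate 1 and INPUT ZT11 replicate 1 (56) moved the INPUT rhythm count, and a lone array is assumed to vary like the others. Of single genes and lists, 1301 of 1328 values for enrichment, 1901 of 1903 for rhythm, 1697 of 1811 for Tim-Dcr and 120 of 146 for lists kept direction and side of the threshold. Of the others, 12 enrichment and 114 Tim-Dcr values were weaker, 2 rhythm values stronger (cwo in INPUT), and of list values 14 weaker and 9 stronger.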

Other observations

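The readings of single genes here were chosen after the values were seen; the counts over other splits were planned. In Tim-Dcr INPUT, vri read 7.46 at ZT3 and 11.04 at ZT15, tim 8.23 and 11.8, and per 6.44 and 8.70, with Clk the other way at 9.22 and 7.06. Each reading is from 1 array, and the difference from wild type was not tested at each time.

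The oocyte transcript osk varied among wild-type INPUT arrays from 3.74 to 9.62 (7.08 ± 1.75, SD, n = 11), while SP had an SD of 0.210. vas, of the same list, stayed near the floor (3.70 ± 0.125).

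Other splits of the samples were counted for each test across probe sets. With IP and INPUT exchanged at random within times, 3 of 100 splits gave as many higher probe sets as the real 563 (highest other 8660), and 1 of 100 as many lower as the real 14443 (highest other 111). Those 2 counts follow the general offset between the fractions, which look separately normalized, so their splits decide nothing. On centred arrays 1 of 100 reached 4086 higher (highest other 560) and 1 of 100 reached 5147 lower (highest other 192). A chance division of the arrays is thus unlikely for the 2 centred counts. The splits cannot tell enrichment with AGO1 from other differences between the fractions, such as any that separate normalization would leave after centring. Of the splits that part all 11 pairs, 10 were drawn and the others gave at most 0. With times reassigned, 1 of 100 assignments, the real one, gave as many INPUT rhythms as the real 92. The highest other was 84, close to it, so chance is unlikely at this number of assignments but not excluded. For IP, 5 of 100 gave as many as the real 144, so chance cannot be excluded at that share. The highest other was 1464, several times the real count, while the median over the other assignments was 0. The cause of the high count was not tested.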
